A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

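Genome-wide transcript levels were measured with Affymetrix Yeast Genome 2.0 arrays in 4 cultures of Saccharomyces cerevisiae strain BY4741, a haploid laboratory strain of mating type a, growing exponentially in rich glucose medium (YPD). Per the labels, 2 cultures received the vehicle and 2 received CG-1521, an inhibitor of histone deacetylases, at 50 μM for 1 h, and the replicates came from independent biological experiments. RNA was prepared with a column kit after enzymatic digestion of the cell wall and labelled with biotin, per the labels' protocols. The groups and the replicate numbers were taken from the sample titles.

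The deposited values were log2 values per probeset, 1 column per array. Per the submitters' processing notes, they were made with Affymetrix Expression Console and RMA, a procedure that corrects background, quantile-normalizes the arrays together and summarises the probes of each probeset. Versions and settings were not given in the sources used here. Quantile normalization gives all arrays nearly the same distribution, so a change of all transcripts in 1 direction would not be visible in these values. The array carries probesets of 2 species, S. cerevisiae and Schizosaccharomyces pombe, and both entered the submitters' normalization.

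The table held 10928 probesets. The platform annotation used here gave a single gene symbol to 7244 of them, several symbols to 1 and none to 3683, of which 166 were control probesets and 3517 were unnamed. Through their gene identifiers, 5498 probesets matched S. cerevisiae genes of the R64 annotation, which was used for names and gene order alone, and 12 symbols were updated through it. Where 47 genes had several probesets, the probeset with the highest mean over the 4 arrays was kept, and probesets of 1 of these genes moved in opposite directions. This left 5449 genes. Of their probesets, 116 carry a suffix that marks probes shared with other sequences, and values of such near-identical copies cannot be separated.

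Background was set for each array as the 95th percentile of 1746 S. pombe probesets, which have no matching species in the samples. It lay between 2.42 and 2.45 on the log2 scale, and 5441 to 5443 genes exceeded it on each array. In both groups 4 genes were at or below background on every array, and 3 more were so in the control group alone. For a gene at or below background on both arrays of 1 group, a fold is a lower bound: the other group's mean against the mean of, per array, the higher of the background and the gene's own value.

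Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, no intensity trend, no replicate block), and p-values were two-sided and Benjamini-Hochberg adjusted over the 5449 genes. A gene was called at an adjusted p under 0.05. The fit had 2 residual degrees of freedom and borrowed 2.69 from the other genes. The number of arrays limits the precision, and the median SE of a log2 fold change was 0.12.

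Before the data were examined, 39 gene lists were fixed, along with the tests, the alternatives and the rule for named genes. Each list was tested with camera of limma at its preset inter-gene correlation of 0.01 on the same fit, with Benjamini-Hochberg adjustment over the 39 lists. Camera with a correlation estimated for each list and fry of limma were alternatives. The former rests on the 2 residual degrees of freedom alone and has little power here. Of 903 list entries, 859 had a probeset, and 15 genes stood in more than 1 list. The ribosomal protein and COS lists were drawn up by a name pattern, which also took in RPP1, a subunit of RNase P, and COS111, and both stayed in. The rule named, in each direction, the 10 called genes with the largest change whose CG-1521 values both lay on the same side of both control values. It added up to 4 members of each list with the smallest p, any called member needed to describe the list, the 5 zinc-dependent histone deacetylases and the markers deleted in the strain. Genes named outside this rule are identified as chosen after their values were seen, apart from the array's control genes and some list members. These members, FET3, FTR1, TIS11, FRE1, ACO1 and CTT1, did not pass and were also named outside the rule.

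The procedure was tested on simulated arrays of the 5449 genes with 200 changed genes, in 20 draws. It recovered 93.9% of genes changed by a log2 value of 2, 57.3% of those changed by 1 and 1.27% of those changed by 0.5, and 4.97% of the calls were false. A list of genes raised by 0.5 was found in 20 of 20 draws, with 2 false calls among all other lists in these draws. Fewer genes changed there than the 1620 called in the data, and noise was drawn separately for each gene. It came from the model fitted to the data, with the same spread in both groups, so the false share largely follows from that model. In the data the median SD was 0.08 between controls and 0.12 between CG-1521 arrays. Recovery and the false share in the data can therefore differ, and the list counts do not cover genes that vary together.

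The other settings were a replicate block, eBayes with trend and robust options, dim genes left out, quantile normalization or median centring over the S. cerevisiae probesets, all features of the table in the fit, the mean of a gene's probesets, shared probesets left out, a fold minimum, other thresholds and each array left out in turn. Same-numbered arrays had deviations from their group means that correlated at -0.26 across genes, which are not independent replicates, so the numbers were not treated as pairs. Spike-in controls were read as quality measures and were not used for scaling. Unnamed and control probesets stayed outside the gene fit.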

Results

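Transcript levels of 5449 genes were compared between 2 control cultures and 2 cultures exposed for 1 h to 50 μM CG-1521, 1 array per culture. Array medians over these genes lay between 9.82 and 9.89 on the log2 scale. Across genes, which are not independent replicates, the arrays correlated at 0.994 within the control group, 0.983 within the CG-1521 group and between 0.932 and 0.956 across groups. The comparison addresses which transcripts change when growing yeast meets a histone deacetylase inhibitor.

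With CG-1521, 17 of 29 genes of the Aft1/Aft2 iron regulon and 27 of 32 Msn2/Msn4 general stress genes rose, and 12 of 23 iron-sulfur and heme enzymes and 45 of 51 ribosome biogenesis genes fell. All 4 lists passed in limma's camera test, and with an estimated correlation none did (adjusted p = 0.594 for the Aft1/Aft2 and ribosome biogenesis lists and 0.596 for the others). In the fry test the iron-sulfur and heme list did not pass (fry adjusted p = 0.0594), and the other lists did. LSO1, a small protein linked to iron deprivation, rose from a mean log2 value of 5.91 ± 0.39 to 11.12 ± 0.22 (SD, n = 2 each), a log2 fold change of 5.21 (SE 0.23, limma adjusted p = 0.00676) or 37.0-fold. FIT1, a cell wall mannoprotein that retains siderophore iron, rose 13.0-fold, from 6.95 ± 0.12 to 10.66 ± 0.32 (SD, n = 2 each). LEU1, the iron-sulfur isomerase of leucine synthesis, fell by 2.33 on the log2 scale (SE 0.14, adjusted p = 0.00676), from 12.23 ± 0.02 to 9.90 ± 0.21 (SD, n = 2 each). PHO5, the repressible secreted acid phosphatase, fell by 2.13 (SE 0.17, adjusted p = 0.00756).

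In all, 703 genes were higher and 917 were lower with CG-1521, 29.7% of those tested. A log2 change of at least 1 was reached by 239 of the higher and 180 of the lower genes. Both CG-1521 values lay on the same side of both control values for every called gene. This was so for 72.3% of all genes tested, where chance gives 33.3%. After LSO1, the largest rises were those of MPC3, a mitochondrial pyruvate carrier subunit (3.99, SE 0.66), FIT1 (3.70, SE 0.19), RTC3 (3.43, SE 0.46), the ribosome-associated TMA10 (3.43, SE 0.30), PHO92, a reader of methylated mRNA (3.14, SE 0.82), YBR284W (2.95, SE 0.47), the small heat shock protein HSP42 (2.90, SE 0.24), RGI2 (2.88, SE 0.44) and SOL4, a 6-phosphogluconolactonase (2.67, SE 0.25). Their adjusted p-values ran up to 0.0481, that of PHO92. For MPC3, PHO92, RTC3, YBR284W and RGI2 the CG-1521 arrays lay far apart, with replicate 1 above replicate 2 by 1.97, 2.35, 1.27, 1.35 and 1.32.

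After LEU1, the largest falls were those of MMP1, an S-methylmethionine permease (-2.21, SE 0.14), BFA1, part of the mitotic exit checkpoint (-2.16, SE 0.15), PHO5, CCP1, the mitochondrial cytochrome c peroxidase (-2.11, SE 0.48), YOR008C-A (-2.09, SE 0.17), YBR238C (-1.90, SE 0.34), SPO74 (-1.84, SE 0.11), HEM13 of heme synthesis (-1.82, SE 0.28) and CYT1, cytochrome c1 (-1.78, SE 0.26). Their adjusted p-values reached at most 0.0357, that of CCP1. Leaving out 1 control array lowered the counts, to 58 higher and 18 lower without control replicate 1 and to 50 and 16 without control replicate 2, and fitting all features of the table together gave 334 and 444. Of 177 named genes that were called, 30 kept the call in every setting in which single genes were followed. Among them were LSO1, FIT1, TMA10, HSP42, SOL4, LEU1, MMP1, BFA1, PHO5, YOR008C-A and SPO74. Most of the remaining named genes lost the call when 1 control array was left out. The hybridization spikes, added before hybridization, had a median of 12.18 and 11.95 on the CG-1521 arrays against 11.35 and 11.79 on the control arrays.

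Of the 39 gene lists, 9 were higher and 5 were lower with CG-1521 in camera with its preset correlation. With an estimated correlation 0 lists were called, and the smallest adjusted p was 0.594. With 2 residual degrees of freedom that setting had little power, so its missing calls speak neither for nor against a list. The fry test, which asks whether a list's genes move in 1 direction on balance without comparing them with other genes, called 8 lists, 6 of them among these 14. The 6 were the Aft1/Aft2, Pdr1/Pdr3, Yap1, Msn2/Msn4, proteasome and ribosome biogenesis lists. The others that fry called were the respiratory chain and the acid and polyamine export lists.

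**Figure D1:**
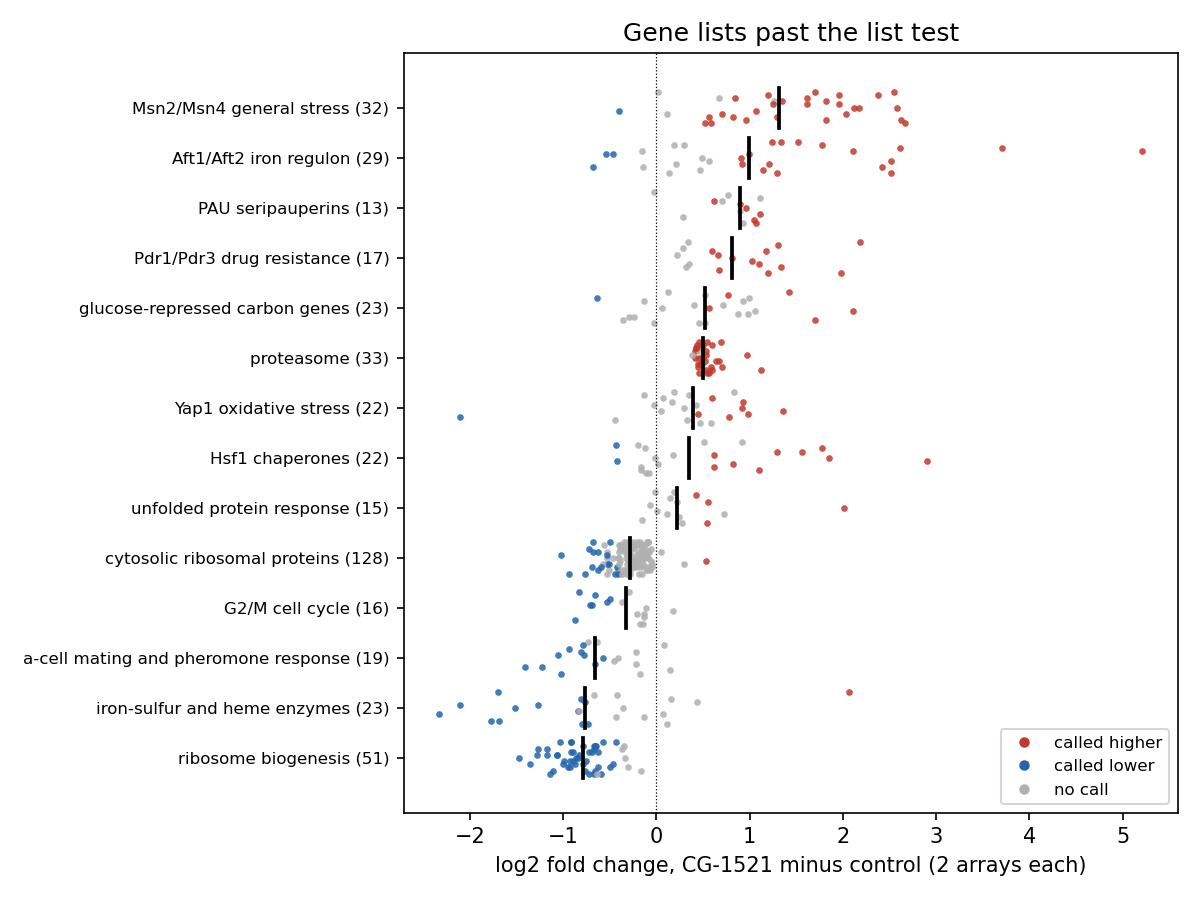
Log2 fold changes (CG-1521 minus control, 2 arrays each) of the members of the 14 lists called by camera, with the number of measured genes in brackets; each point is a gene, red if called higher, blue if called lower and grey without a call, and black bars are list medians. Medians ran from -0.79 for ribosome biogenesis to 1.32 for the Msn2/Msn4 list.

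Iron genes moved in both directions. In the Aft1/Aft2 iron regulon, the genes switched on by the iron-sensing activators, 17 of 29 measured genes rose, 3 fell and 9 did not pass, with a median log2 fold change of 0.99 (camera adjusted p = 5.93e-08, and adjusted p = 0.594 with an estimated correlation). Adjusted over the list alone, 18 rose and 3 fell. HMX1, a heme oxygenase, rose by 2.61 (SE 0.10), and the mannoprotein FIT2 rose by 2.51 (SE 0.16). The siderophore transporters ARN1, ARN2, ENB1 and SIT1 rose too, by 1.30, 2.11, 1.77 and 1.24, as did the reductases FRE2, FRE3 and FRE5. The members that fell were CTH1 (-0.68), an mRNA-binding protein, SMF3 (-0.54), a vacuolar metal transporter, and FRE4 (-0.47). The high-affinity uptake pair FET3 (0.48, adjusted p = 0.062) and FTR1 (0.47, adjusted p = 0.136) did not pass, and neither did TIS11 (-0.14) or FRE1 (-0.16). FET3 was already at 11.77 ± 0.23 in the control cultures (SD, n = 2).

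Of 23 iron-sulfur and heme enzymes, 12 fell, 1 rose and 10 did not pass, with a median of -0.76 (camera adjusted p = 0.00195, and adjusted p = 0.596 with an estimated correlation). Adjusted over the list alone, 13 fell and 2 rose. Beside LEU1 these included LYS4, homoaconitase (-1.27, SE 0.10), LIP5, lipoyl synthase (-1.70, SE 0.15), and RLI1, an essential iron-sulfur ATPase of ribosome recycling (-1.68, SE 0.24). BNA2, a heme enzyme that opens NAD synthesis from tryptophan, rose by 2.07 (SE 0.37). Aconitase, ACO1, stood at 0.11 and did not pass. Among 32 respiratory chain and ATP synthase genes 9 fell and 0 rose, including COX6 (-1.62), QCR2 (-1.10), COX4 (-0.98) and CYT1. The list did not pass in camera (median -0.28, camera adjusted p = 0.109) but passed in fry (fry adjusted p = 0.0455). That list passed without CG-1521 replicate 2 (adjusted p = 0.0458).

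**Figure D2:**
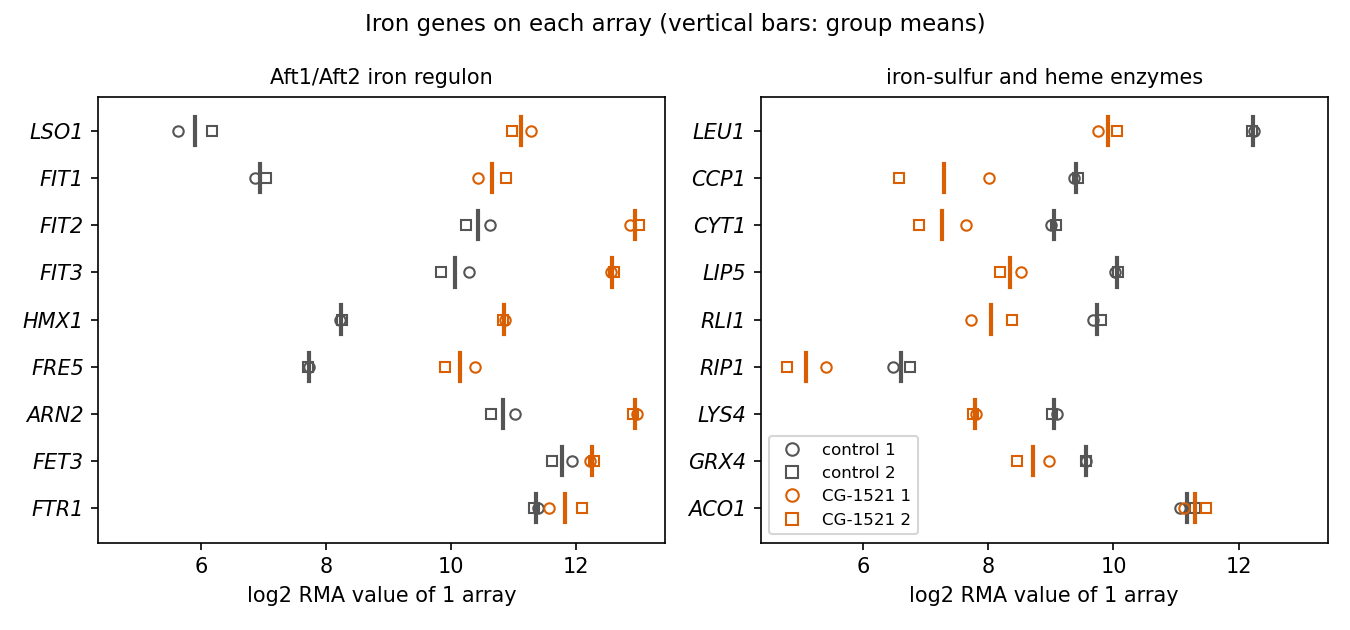
Log2 RMA values on each of the 4 arrays for 9 genes of the Aft1/Aft2 regulon (left) and 9 iron-sulfur or heme enzymes (right); circles are replicate 1, squares replicate 2, grey control, orange CG-1521, and vertical bars group means. LSO1 moved from 5.91 to 11.12 and LEU1 from 12.23 to 9.90, while FET3, FTR1 and ACO1 did not pass the test.

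Lists for the other metals did not pass. In the Zap1 zinc regulon 1 of 19 genes rose and 4 fell, with a median of -0.14 (camera adjusted p = 0.653). The zinc transporter ZRT1 fell 1.99-fold, ZRT2 (-0.79, SE 0.11), ZRC1 (-0.51, SE 0.12) and the alcohol dehydrogenase ADH4 (-1.01, SE 0.17) fell too, and the membrane protein IZH4 rose by 1.08. In the copper regulon 1 of 11 genes rose, CUP2 (0.49), and 2 fell, IRC7 (-1.26) and FRE7 (-1.02), with a median of -0.16 (camera adjusted p = 0.827).

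General stress genes rose broadly, and chaperone genes rose in part. In the Msn2/Msn4 general stress list 27 of 32 genes rose, 1 fell and 4 did not pass, with a median of 1.32 (camera adjusted p = 1.11e-12, and adjusted p = 0.596 with an estimated correlation); adjusted over the list alone, 29 rose and 1 fell. Phosphoglucomutase PGM2 rose by 2.17 (SE 0.10), STF2 by 2.03 (SE 0.10), polyubiquitin UBI4 by 2.12 (SE 0.11) and glucokinase GLK1 by 2.58 (SE 0.15). The member that fell was SOD2 (-0.40), mitochondrial superoxide dismutase, and the catalase CTT1 (0.11) did not pass. The list's median was higher on CG-1521 replicate 1 than on replicate 2, by 0.23. Of 22 Hsf1 chaperones 9 rose, 2 fell and 11 did not pass, with a median of 0.35 (camera adjusted p = 0.0318, and adjusted p = 0.619 with an estimated correlation). The disaggregase HSP104 rose by 1.10 (SE 0.10), HSP26 by 1.77 (SE 0.15) and HSP78 by 1.30 (SE 0.15), while the co-chaperone YDJ1 (-0.42) and SSA2 (-0.44) fell. Adjusted over the list alone, 10 chaperones rose and 2 fell.

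Proteasome genes moved together by a small amount. Of 33 genes 31 rose and 0 fell, with a median of 0.50 (camera adjusted p = 4.5e-12, and adjusted p = 0.596 with an estimated correlation), and all 33 rose when adjusted over the list alone. Their transcription factor RPN4 rose by 1.12 (SE 0.11), and the subunits PRE4, RPN12 and PUP1 rose by 0.97, 0.70 and 0.64. In the unfolded protein response list 4 of 15 genes rose and 0 fell (median 0.22, camera adjusted p = 0.0291, and adjusted p = 0.706 with an estimated correlation), both over all genes and adjusted over the list alone. INO1, inositol phosphate synthase, rose by 2.01 (SE 0.27), and PDI1, MPD1 and HRD1 rose by 0.55, 0.54 and 0.42. Its call ended without control replicate 2 (adjusted p = 0.0546) and without CG-1521 replicate 2 (adjusted p = 0.149).

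Most genes of the multidrug resistance list rose, and a smaller part of the oxidative stress list did. In the Pdr1/Pdr3 list, regulators and targets of multidrug resistance, 12 of 17 genes rose and 0 fell, with a median of 0.81 (camera adjusted p = 9.16e-08, and adjusted p = 0.594 with an estimated correlation), also when adjusted over the list alone. The largest were ICT1, a lysophospholipid acyltransferase (2.18, SE 0.13), and CIS1 (1.98, SE 0.11), and the transporters YOR1 and PDR10 rose by 1.33 and 1.30. In the Yap1 list 7 of 22 genes rose and 1 fell, with a median of 0.39 (camera adjusted p = 0.00157, and adjusted p = 0.594 with an estimated correlation), also when adjusted over the list alone. YAP1 itself rose by 0.92 (SE 0.12), thioredoxin TRX2 by 0.78 (SE 0.10), AAD4 by 0.93 and OYE3 by 0.98, and the member that fell was CCP1. In the list of acid and polyamine exporters 4 of 13 genes fell, TPO5 (-0.61), QDR1 (-0.90), AQR1 (-0.84) and TPO2 (-0.47). The list did not pass in camera (median -0.47, camera adjusted p = 0.122) but passed in fry (fry adjusted p = 0.0218).

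Ribosome biogenesis genes fell. In this list 45 of 51 genes fell and 0 rose, with a median of -0.79 (camera adjusted p = 2.25e-15, and adjusted p = 0.594 with an estimated correlation), and 48 fell when adjusted over the list alone. Those with the smallest p were FAF1, a factor of small-subunit assembly (-1.48, SE 0.10), NOP7 (-1.28, SE 0.10), RRP5 (-1.06, SE 0.10) and NIP7 (-1.07, SE 0.10). Cytosolic ribosomal protein genes were lower by less: 17 of 128 fell and 1, RPL15B (0.53), rose, with a median of -0.28 (camera adjusted p = 1.78e-07, and adjusted p = 0.791 with an estimated correlation). Adjusted over the list alone, 0 passed. Those that fell included RPS28B (-1.02, SE 0.15), RPS0B (-0.94, SE 0.18) and RPS23B (-0.59, SE 0.11). The name pattern's stray member RPP1 fell by 0.69, and without it 16 fell. Many ribosomal protein genes come in near-identical pairs, whose values are uncertain for the single copy.

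Genes of a-cell mating and the pheromone response, held together in 1 list, fell. Of 19 genes 10 fell and 0 rose, with a median of -0.65 (camera adjusted p = 0.000507, and adjusted p = 0.619 with an estimated correlation), and 13 fell when adjusted over the list alone. They included SST2, the negative regulator of pheromone signalling (-1.22, SE 0.10), FIG1 (-1.41, SE 0.12), the kinase FUS3 (-0.94, SE 0.15) and the agglutinin AGA1 (-1.02, SE 0.17). Among 4 alpha-cell markers MF(ALPHA)1 fell by 0.75 to a mean log2 value of 2.87, close to background, and 0 rose (median 0.04, mean -0.14, camera direction down, adjusted p = 0.894). MF(ALPHA)2 and SAG1 had signal well above background, at means of 9.28 and 7.72 in control and 9.40 and 7.77 with CG-1521. In the G2/M cell cycle list 7 of 16 genes fell and 0 rose, also when adjusted over the list alone, with a median of -0.33 (camera adjusted p = 0.0115, and adjusted p = 0.596 with an estimated correlation). They included the cyclin CLB2 (-0.87, SE 0.16), SPO12 (-0.83, SE 0.14), the transcription factor SWI5 (-0.72, SE 0.14) and the septum chitin synthase CHS2 (-0.66, SE 0.11). In the G1/S list 8 of 26 genes fell, led by CLB6 (-1.05), POL12 (-0.69), CLN1 (-0.59) and NRM1 (-0.59), and 2 rose, RFA2 (0.41) and RFA3 (0.49). It did not pass (median -0.28, camera adjusted p = 0.0648), but passed without CG-1521 replicate 1 (adjusted p = 0.0285) and without control replicate 2 (adjusted p = 0.0378). In the M/G1 list 2 of 19 fell, MCM5 (-0.46) and AMN1 (-0.45), and 0 rose (median -0.22, adjusted p = 0.319).

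Histone genes and the deacetylases themselves showed few calls. Of 9 histone genes 0 were called, with a median of -0.08 (camera adjusted p = 0.839), and the member with the smallest p was HTZ1 (-0.22, adjusted p = 0.174). Of 20 deacetylases and partner subunits 2 fell and 0 rose, with a median of 0.02 (camera adjusted p = 0.839), and 0 passed when adjusted over the list alone. These were the deacetylase HDA1 (-0.49, SE 0.13, adjusted p = 0.0472) and the silencing protein SIR4 (-0.46, SE 0.10). RPD3 stood at 0.01 (SE 0.10), HOS1 at 0.79 (SE 0.21, adjusted p = 0.0522), HOS2 at -0.27 (SE 0.12) and HOS3 at 0.03 (SE 0.26), and none of these 4 passed.

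Genes under Ume6, which recruits the Rpd3 deacetylase to meiotic genes in growing cells, did not pass as a list. Of 26 early meiotic genes 3 rose and 1 fell, with a median of 0.30 (camera adjusted p = 0.21), and 2 rose when adjusted over the list alone. DMC1, the meiotic recombinase, rose by 1.33 (SE 0.24), SPO13 by 1.76 (SE 0.33) and NDT80, the middle sporulation activator, by 1.12 (SE 0.28), and MEI4 fell by 1.03 (SE 0.22). Of 21 middle and late sporulation genes 2 rose, OSW2 (1.77) and SPS100 (1.54), and 2 fell, SPS4 (-1.32) and SPO77 (-0.83), with a median of 0.30 (camera adjusted p = 0.21). Both lists were higher on CG-1521 replicate 1 than on replicate 2, by a median of 0.55 and 0.50, and both passed without CG-1521 replicate 2 (adjusted p = 0.00576 and 0.0158).

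Glucose-repressed carbon genes passed with a like gap between the treated arrays. Of 23 genes 5 rose and 1 fell, also when adjusted over the list alone, with a median of 0.52 (camera adjusted p = 0.0193, and adjusted p = 0.791 with an estimated correlation). The hexose transporter HXT5 rose by 2.11 (SE 0.20), the peroxisomal enzyme FOX2 by 0.56 (SE 0.10) and the aldehyde dehydrogenase ALD4 by 1.42 (SE 0.25), and the transporter HXT4 fell by 0.63 (SE 0.11). The list's median was higher on CG-1521 replicate 1 than on replicate 2 by 0.53, and its call ended without CG-1521 replicate 1 (adjusted p = 0.0715). Hybridization spikes differed between these arrays by 0.23, and poly-A spikes by 0.52, with replicate 1 higher.

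**Figure D3:**
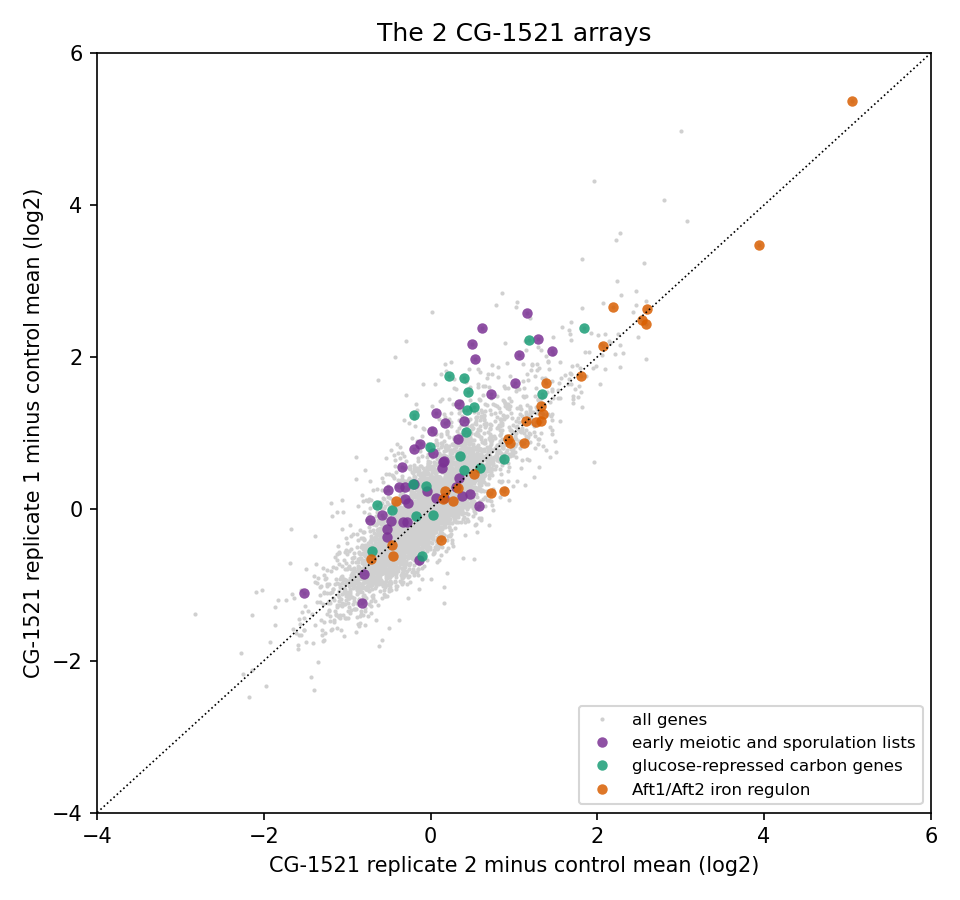
Each point is a gene, with its value on CG-1521 replicate 2 (horizontal) and on CG-1521 replicate 1 (vertical), both minus the control mean on the log2 scale; the dotted line marks equality. Early meiotic, sporulation and glucose-repressed genes lie mostly above the line, with median gaps of 0.55, 0.50 and 0.53, and the Aft1/Aft2 genes lie along it, with a median gap of -0.05.

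PAU genes, a family of near-identical cell wall proteins mostly near chromosome ends, rose. Of 13 measured genes 6 rose and 0 fell, with a median of 0.90 (camera adjusted p = 8.74e-05, and adjusted p = 0.596 with an estimated correlation), and 10 rose when adjusted over the list alone. PAU14, PAU4, PAU18 and PAU3 rose by 1.07, 1.05, 1.11 and 0.96. Of these probesets 11 are shared with other sequences, so single copies are uncertain, and the call ended when shared probesets were left out, which left 3 genes with a median of 0.62 (adjusted p = 0.296). Of 9 COS genes, another family near chromosome ends, COS4 rose (0.46) and COS12 fell (-1.39), and the list did not pass (median 0.04, mean -0.09, camera direction up, adjusted p = 0.839). Of 4 flocculin genes 0 were called (median -0.16, adjusted p = 0.43), and FLO10 had the smallest p (-0.57, adjusted p = 0.0827).

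Other metabolic lists did not pass, though members changed. In the PHO phosphate regulon 3 of 15 genes fell, PHO5, PHO11 (-1.52) and the polyphosphate synthesis subunit VTC3 (-0.74), and PHM8 rose by 0.55 (list median -0.30, camera adjusted p = 0.0892). That list passed without control replicate 1 (adjusted p = 0.02). In the sulfur and methionine list 7 of 21 fell, among them MMP1, MET6 (-1.56), SAM1 (-1.45) and SAM3 (-1.08), and 1 rose, MUP3 (1.07), with a median of -0.27 (adjusted p = 0.443). Of 14 TCA cycle genes 6 rose, including IDH1 (1.06), CIT1 (1.06) and LSC2 (0.88), and 3 fell, including the succinate dehydrogenase anchor SDH4 (-0.74), with a median of 0.15 (adjusted p = 0.259). Of 18 glycolysis and fermentation genes TDH1 rose by 2.11 (SE 0.11) and PDC5 by 0.58, and 0 fell (median -0.07, mean 0.04, camera direction down, adjusted p = 0.956). Of 26 ergosterol genes 4 fell, led by ERG11, the lanosterol demethylase (-1.32, SE 0.12), with ERG5 (-0.91) and ERG7 (-1.05), and ERG27 rose by 0.60 (median -0.14, adjusted p = 0.511). Of 18 hypoxic and Rox1-repressed genes 5 fell, among them HEM13, SUT1 (-1.26) and YHB1 (-1.21), and 3 rose, among them COX5B (0.79), with a median of -0.13 (adjusted p = 0.577).

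In the Gcn4 list of amino acid synthesis 5 of 33 genes fell, led by BAT1 (-1.05), ARO3 (-0.91) and ARG8 (-0.77), and ARG1 rose by 0.50 (median -0.18, adjusted p = 0.21). Of 16 NAD and thiamine genes 5 rose, led by BNA2, THI13 (1.19) and BNA6 (0.57), and 2 fell, among them PHO3 (-1.62), a phosphatase that cleaves thiamine phosphates (median 0.32, adjusted p = 0.127). In the DNA damage list 4 of 16 rose, among them the glycosylase MAG1 (1.47, SE 0.14) and PHR1 (0.55), and 2 fell, RNR2 (-0.87) and RNR4 (-0.60), which form the small subunit of ribonucleotide reductase (median 0.17, adjusted p = 0.319). Of 16 cell wall integrity genes 2 rose, GSC2 (1.40) and YPS1 (1.07), and 2 fell, CHS3 (-0.84) and PRM5 (-0.78), with a median of 0.11 (adjusted p = 0.45). That list passed without CG-1521 replicate 1 (adjusted p = 0.0461). Of 6 galactose genes GAL10 (0.66) and GAL3 (0.71) rose and 0 fell (median 0.45, adjusted p = 0.21).

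The markers deleted in the strain checked the identity of the cultures. MET17 had mean log2 values of 1.96 in control and 1.90 with CG-1521, and URA3 of 1.39 and 1.32, all below background. LEU2 stood at 2.25 ± 0.24 in control, below background, and at 2.93 ± 0.22 with CG-1521 (SD, n = 2 each), at least 1.40-fold higher (adjusted p = 0.0488). As LEU2 is among the deleted markers and its values lie close to background, this call is not read as a rise of its transcript. HIS3, whose deletion in this strain removes part of the gene, stood at 10.83 ± 0.11 and fell by 0.60 (SE 0.11), so its probeset checks nothing. As a list these 4 markers did not pass (median -0.07, adjusted p = 0.875).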

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

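Tests of array scaling, zinc and iron shortage, and of a stronger exposure of culture 1, were chosen after the result was seen, and the other tests of this part were written down before. Bootstrap intervals in this part resampled the genes of a list. They describe the spread between genes, which are not independent replicates, and not the spread between cultures.

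Unnamed probesets, which stayed outside the gene fit, held changes between the groups. Of 423 that exceeded background on at least 2 arrays, 11 were higher and 8 were lower with CG-1521 at an adjusted p under 0.05. The probeset 1770519_at was lower by a log2 value of -3.26 (SE 0.34), 1775737_at by -1.99 (SE 0.16), and 1769544_at and 1776865_at were higher by 2.22 (SE 0.34) and 2.17 (SE 0.15). The array's own control probesets for 3 yeast genes, also outside the fit, differed as well. Those of RIP1 had a mean change of -1.67 over 3 probesets, from -1.38 at the 3′ end to -2.01 at the 5′ end, and those of TDH1 a mean change of 2.12, where the genes' own probesets gave -1.52 and 2.11. Those of SPT15 had a mean change of -0.69, from -0.50 at the 3′ end to -0.82 at the 5′ end, and its own probeset gave -0.66.

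The iron genes are a pattern to follow: the Aft1/Aft2 regulon was higher and iron-sulfur and heme enzymes were lower. Array scaling that depends on signal is argued against as the whole account by the level of random lists matched on mean signal. The middle 95% of their medians ran from -0.24 to 0.15 for the first list and from -0.25 to 0.24 for the second. The lists themselves had medians of 0.99 and -0.76, and 0 of 10000 matched lists lay as far out as either. Both lists had already passed camera against the other genes, and random lists draw genes singly, whereas genes of 1 list can vary together. The counts of matched lists in this paragraph therefore do not measure how unusual a list is. A shortage of zinc along with iron was not borne out, because the Zap1 regulon had a median of -0.14 (bootstrap 95% interval -0.46 to 0.20), below 0.49, which is 1 in 2 of the Aft median. A shortage of iron within the cell may account for the pattern, as a hypothesis: among 32 further iron-dependent and iron-sulfur assembly proteins 14 fell and 1 rose, and 2 of 10000 matched lists had a median as low as -0.41. That list was drawn up with many values already seen, and HEM13, MET13, RNR4 and SPO24 were taken out of it after a first run as not clearly iron-dependent (HEM13 and RNR4 fell and SPO24 rose by 1.57; with them, 0 of 10000 matched lists were as low). Its camera adjusted p was 0.0945 with an estimated correlation, adjusted only over the lists drawn up after the values were seen. This value cannot be set beside those of the 39 fixed lists. Within the Aft list 17 members rose, but 3, CTH1, SMF3 and FRE4, were called lower, against the direction of the list. FET3, FTR1 and TIS11, known Aft targets, did not pass. FET3 and FTR1 lay above control and TIS11 below, and the missing calls do not show whether these targets responded. They lend the hypothesis no support.

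The gap between the CG-1521 arrays in meiotic, sporulation and glucose-repressed genes is another. An offset between the arrays that depends on signal is argued against as the whole account by the level of the matched lists. The middle 95% of their median gaps ran from 0.00 to 0.24, below the 0.53 of these 70 genes, which 0 of 10000 reached. For the 3 lists alone, 4, 73 and 0 matched lists were as high. These 3 lists had the largest gaps of all the fixed lists, and the counts make no allowance for that choice. Random lists also draw genes singly, whereas genes of 1 list can vary together. The counts therefore do not measure how unusual the gap is. A stronger exposure of culture 1 stays open, because the other induced lists went both ways: all 46 measured Aft and Pdr genes had a median gap of -0.0701 (bootstrap 95% interval -0.15 to -0.00892), while the Msn2/Msn4 list was higher on array 1 by 0.23 (0.04 to 0.48) and the PAU genes by 0.28. The control arrays differed as well: the median array 1 minus array 2 was -0.06 for early meiotic, -0.32 for sporulation, -0.29 for glucose-repressed and -0.22 for Msn2/Msn4 genes. Most of these lists thus varied between cultures without the compound too. Ribosomal RNA probesets had a CG-1521 array 1 minus array 2 of -0.91, and whether this bears on the gap was not tested. A difference in growth or sugar supply between the cultures stays open too and was not tested.

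A further pattern is that of the PAU genes. Other genes near chromosome ends, the 10 nearest each end without PAU and COS genes, were higher as a set, with a median of 0.17 over 208 genes (bootstrap 95% interval 0.04 to 0.26, limma camera adjusted p = 0.00322 as a single list, 46 called higher and 25 lower). The bound written beforehand for a rise too small to account for the PAU genes was 0.45, and the interval lies below it, although the camera p written as the sign of such a rise was met too, and following the bound was decided after both were seen. A uniform rise near chromosome ends therefore may add to the PAU change without accounting for all of it. Whether copies rose singly or share hybridization cannot be told apart, since the SD between copies was 2.13 times the SE of 1 gene and 11 of 13 probesets are shared.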

How the results depend on the processing

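The crossed pairs and the lists without RPP1 and COS111 were chosen after seeing the data, and single genes were not followed in them. The replicate block gave 369 higher and 450 lower genes and the same 14 list calls. Crossing the pairs gave 842 and 978 genes, with 9 and 5 lists. With all features in the fit 334 genes were higher and 444 lower, and 9 lists were lower, the added ones being the PHO, respiratory chain, G1/S and acid and polyamine export lists. A log2 change of at least 1 left 239 and 180 genes, and an adjusted p under 0.01 left 128 and 118, both by construction. Leaving out each array in turn gave 50 to 1001 higher and 16 to 1133 lower genes. The lowest counts were those without a control array, where the lone array was assumed to vary like the CG-1521 pair, whose median SD was 0.12 against 0.08 between controls. List calls in these fits numbered 8 to 10 higher and 6 lower. Camera with an estimated correlation called 0 higher and 0 lower lists, and fry called 5 and 3. For the block, all features and fry, the cause was not tested. The remaining settings moved no count by over 1.5 times: higher genes ran from 699 to 999 and lower genes from 887 to 1326. Of the 1620 genes called, 0 changed sign in any setting, which was largely fixed in advance. The block, the eBayes options, all features and the thresholds leave fold changes as they were. With an array left out no sign could change, since both CG-1521 values of every called gene lay on the same side of both control values. Of the 177 named genes that were called, the block ended 47 calls, all features 50, and the array left out between 9, for CG-1521 replicate 2, and 145, for control replicate 2. With 5441 to 5443 genes above background on each array, few genes were dim by this measure, and leaving out dim genes gave 704 and 918. Exceeding this background does not by itself show that a transcript was present. The alpha-cell markers MF(ALPHA)2 and SAG1 exceeded it in this strain of mating type a.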

Other observations

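The lists in this part were drawn up after the values were seen, and so were the single genes. Camera p-values of these lists were adjusted over them and the list of further iron-dependent proteins alone. They cannot be set beside those of the 39 fixed lists. Nucleotide genes were lower as a set: of 28 genes of purine and pyrimidine synthesis and salvage 18 fell and 0 rose, with a median of -0.58 (camera adjusted p = 1.05e-06, and adjusted p = 0.0945 with an estimated correlation). They included the salvage enzymes FUR1 (-1.51), HPT1 (-1.48) and AAH1 (-1.56) and the CTP synthase URA7 (-1.59, SE 0.15). Genes of vacuolar breakdown were higher: of 23 hydrolases and autophagy genes 13 rose and 0 fell, with a median of 0.55 (camera adjusted p = 6.19e-07, and adjusted p = 0.0945 with an estimated correlation). The vacuolar mannosidase AMS1 rose by 2.12 (SE 0.16) and protease PRB1 by 2.07 (SE 0.18), while the autophagy kinase ATG1 stood at -0.12 and did not pass.

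Further single genes changed, some of them linked to iron. CCC1, which moves iron into the vacuole, fell by 1.62 (SE 0.10), and the iron-sulfur carrier NFU1 fell by 1.61 (SE 0.10). ELP3, an iron-sulfur enzyme of tRNA modification, fell by 1.39 (SE 0.11) and CIR2 fell by 1.55 (SE 0.35). FMP23, a mitochondrial protein, rose by 2.17 (SE 0.12), and ECM4, a glutathione transferase, rose by 2.27 (SE 0.16).

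Ribosomal RNA probesets had a median of 10.27 on CG-1521 replicate 1 against 11.18 on control replicate 1, 11.29 on control replicate 2 and 11.18 on CG-1521 replicate 2. The 3′ over 5′ difference of the ACT1 control probesets was 1.73 and 1.72 on the CG-1521 arrays and 1.59 and 1.47 on the control arrays.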
